A study of Rattus norvegicus with 9 samples.

How the data were processed

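RNA from the gastrocnemius, a hindlimb calf muscle, of male Sprague-Dawley rats was measured on 9 spotted two-colour arrays. Each array set RNA of aged rats, 30 months old, against RNA of adult rats, 4 months old. The aged RNA of 3 arrays came from rats ranked stage I, that of 3 arrays from stage II and that of 3 arrays from stage III. The stages rank sensorimotor decline by weight bearing and gait, from some signs at stage I to severe gait aberrations at stage III. On 1 array of each stage the dyes were swapped, so that the aged RNA carried Cy3 instead of Cy5. The groups were taken from the label of the aged channel, and replicates were numbered in accession order within a stage, so a number pairs no samples.

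The values used are the deposited log ratios, 1 per feature and array, taken here as log2. Per the series' design text, the authors read the images with GenePix Pro, took mean spot intensity minus background, and kept spots at least 1.6 times above background. They then scaled the Cy5 channel to a mean log ratio of 0 and normalized each array with LOWESS in the SMA package for R. LOWESS centres each array, so every ratio is relative to the bulk of features on that array, and a shift shared by most transcripts would not be seen. The base of the logarithm is not given in the sources used here. Every log2 value and fold below assumes base 2, and the tests do not depend on it. The most extreme deposited value, -9.04, would be a 526-fold difference in base 2 and an 8434-fold difference in base e. Intensities, backgrounds, slide layout and scan dates were not used here, so no filter on dim spots and no batch other than dye could be examined.

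Per the labels, the values of the dye-swapped arrays were inverted before further processing, and the deposited values were used as they stand, as aged over adult. A rule set beforehand would have turned their sign if each of the 3 swapped arrays had correlated below -0.3 with the mean of its stage's other arrays. The correlations across features were 0.87, 0.95 and 0.96 for stages I, II and III, and no sign was turned.

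The table holds 6240 features, of which 2493 have a value on no array and 1621 on all 9. Features with values on at least 2 of 3 arrays of every stage were tested, following the filter in the design text, which left 2404. Another 1343 features had values but did not pass this filter. The feature IDs are clone-style codes. The files do not pair them with genes, and 0 of the 6240 matched an identifier in the RefSeq gene table for the rat assembly GRCr8. Gene names were therefore not used here, and 25 gene lists fixed beforehand (fibre types, denervation, energy metabolism, protein breakdown, matrix, iron, antioxidants, other cell types and others) were not analysed here. The rule for named genes asked for features with 1 gene symbol, so it named none. In its place the 2 features with the largest rise and the 2 with the largest fall that passed the test with 1 sign on every measured array are given by ID, a choice made after the data were examined.

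One mean per stage was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the stages share an estimate of spread. Contrasts were the mean of the 3 stage means against 0, each stage mean against 0, and each difference between stages. A moderated F test covered any difference among the 3 stages. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 is called passing. The adult RNA is the other channel of every array, so a ratio tested against 0 leaves out the spread among adults. The design text counts 7 aged and 5 adult rats for 9 arrays and does not tie animals to arrays. Some arrays must therefore share an animal, whether or not RNA was pooled. P-values measure the spread between arrays and are too small as tests over animals. No depth can be given for arrays, and their number limits the precision. Arrays held values for 1902 to 3367 features.

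On simulated data with the real spread and 2404 features, 200 of them changed, the test of all stages against adult recovered 86.6% of changes of 0.5, 97.0% of changes of 1 and 100.0% of changes of 2 on the log2 scale, and 6.44% of its calls were false. The test of stage III against stage I recovered 8.96%, 71.6% and 95.5% of the same sizes, and 2.5% of its calls were false. For stages I, II and III against adult the false share was 4.32%, 3.64% and 5.65%. Each test had a single simulated data set with 66 or 67 changes of each size, so these shares are imprecise. The noise was drawn independently for each array, with no animal shared between arrays. In the real data 1886 features passed over all stages, far more than the 200 changed here. The shares therefore need not carry over to the real comparisons with adult muscle.

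The width of an array's ratios was its regression slope on the mean of all 9 arrays over the 1621 features measured on each. Widths were compared by exact permutation of the arrays. Alternatives set before the data were examined were median centring, scaling to one median absolute ratio, quantile normalization, a dye term, swapped arrays turned or left out, stricter and looser filters on missing values, robust spread, array weights, fits restricted to the stages compared, a SAM-type test written for this work after the authors' use of SAM at a q of 5%, a plain t-test, other thresholds, and leaving out each array. Division by width and removal of ID series medians were added after seeing the data. Averaging of rows of one gene and tests of gene lists could not be run without gene names.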

Results

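The series compared gene expression in the gastrocnemius muscle of 30-month-old rats with that of 4-month-old adults, and asked how the aged profile varied with the severity of gait decline. There were 3 arrays for stage I, 3 for stage II and 3 for stage III. Each array gave log2 ratios of aged over adult RNA. The number of features with a value ranged from 1902 on stage I replicate 1 to 3367 on stage II replicate 2. Median ratios lay between -0.003 and 0.022 on all 9 arrays, as LOWESS normalization sets them. Features are spotted probes known here by ID only.

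The first comparison asked which transcripts differed between aged and adult muscle whatever the stage. Of 2404 features tested over all stages, 1886 passed (78.5%, limma, adjusted p under 0.05). Of these, 941 were higher and 945 lower in aged muscle. Large changes were more often falls than rises. Among passing features, 307 were lower and 205 higher by more than 1 log2 unit, and 75 were lower and 28 higher by more than 2 log2 units. The median size of the passing changes was 0.63 log2 units, against a median standard error of 0.08. Of the 1621 features measured on every array, 945 (58.3%) had 1 sign on all 9 arrays, where independent signs would give 0.39%. The design text counts 5 adult rats for 9 arrays, so some arrays must share an adult and the signs are not independent. In 100 simulations with no effect but a single shared adult RNA that deviated as much as arrays within a stage, the share averaged 20.3%, and a larger deviation would raise it. The 20.3% follows from this assumed size, with 1 spread for all features, and is no baseline measured in these data.

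The features with the largest rises were RNABU29 and RNABO13. RNABU29 was 5.00 ± 0.09 log2 units higher in aged muscle (SE, n = 9 arrays, limma adjusted p = 3.97e-11). Its stage means were 4.11 ± 0.48, 5.30 ± 0.18 and 5.59 ± 0.06 for stages I, II and III (SD, n = 3 each). RNABO13 was 4.56 ± 0.19 higher (SE, n = 8, limma adjusted p = 2.39e-08), which is 23.6-fold. It had 3.08 ± 0.33 at stage I (SD, n = 2), 4.57 ± 0.32 at stage II (n = 3) and 6.04 ± 1.01 at stage III (n = 3). The largest falls were those of RGIBC39 and RNABQ01. RGIBC39 stood at -4.22 ± 0.41 (SE, n = 9, limma adjusted p = 3.48e-06), with stage means of -2.59 ± 1.84, -5.06 ± 0.78 and -5.02 ± 1.90 for stages I, II and III (SD, n = 3 each), and its single arrays ranged from -7.20 to -0.91. RNABQ01 stood at -4.16 ± 0.08 (SE, n = 9, limma adjusted p = 8.13e-11), with stage means of -4.10 ± 0.21, -3.89 ± 0.25 and -4.49 ± 0.33 (SD, n = 3 each) and single arrays between -4.79 and -3.70.

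These calls rest on the swapped arrays being aged over adult as the labels state. A common dye term left 1822 features, and the 6 arrays with aged RNA in Cy5 alone gave 1229 of 1673 testable features. With the sign of the swapped arrays turned, 0 features passed in limma and 9 had an unadjusted p under 0.05.

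Each stage was then compared with adult muscle on its own. At stage I, 1172 of 2404 features passed (48.8%), 587 higher and 585 lower. At stage II, 1499 passed (62.4%), 734 higher and 765 lower. At stage III, 1659 passed (69.0%), 815 higher and 844 lower. The median absolute ratio over all tested features was 0.38 at stage I, 0.50 at stage II and 0.62 at stage III. Passing features more than 1 log2 unit away from 0 numbered 326 at stage I, 560 at stage II and 711 at stage III. These counts against adults do not by themselves test a difference between stages. Most of their rise went with array width, whatever its origin. After quantile normalization between arrays, 1406, 1470 and 1486 features passed at stages I, II and III. With the spread taken from each feature's own 3 arrays alone, 1, 497 and 857 features passed at stages I, II and III.

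The stage profiles resembled one another. A set of 993 features passed at all 3 stages in 1 direction, 491 higher and 502 lower, and 24 features passed in opposite directions at 2 stages. Stages II and III shared 644 of their higher and 685 of their lower features, where independent lists of those sizes would share 249 and 269. Stages I and III shared 522 higher and 526 lower features, against 199 and 205. Stages I and II shared 517 higher and 536 lower features, against 179 and 186. Across features, which are not independent replicates, the correlation of stage means was 0.92 for I and II, 0.90 for I and III and 0.95 for II and III. All stages were set against adult RNA, which may be shared. In 100 simulations with no effect but a single shared adult RNA that deviated as much as arrays within a stage (SD 0.32), the correlation averaged 0.73 to 0.74. This value too follows from the assumed size of the deviation and is no baseline measured in these data. The observed covariances of 0.64, 0.75 and 1.01 exceeded the simulated 0.10 by 0.54, 0.65 and 0.90. The adults could not be split to remove this share, so part of the resemblance may come from them.

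The last comparisons asked whether the aged profile itself differed between stages. Between stages III and I, 372 of 2404 features passed (15.5%, limma), 171 higher and 201 lower at stage III. The balance of directions depended on the setting, with 35 higher and 14 lower at an adjusted p under 0.01 and 263 and 412 with array weights. Of the 372, 349 (93.8%) had a larger absolute ratio at stage III than at stage I, and 23 a smaller one. Among all 2404 tested features the absolute ratio was larger at stage III for 1811 (75.3%). The sign of the difference was that of the stage II ratio, which took no part in the contrast, also for 349 of the 372, against 1780 of all 2404 tested features (74.0%), and 340 of the 372 met both descriptions. Below the adult level at both stages were 164 of the 372, and above it at both stages 147. The other 61 had opposite signs at stages I and III, and 12 of these passed against adult at both stages.

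Stages II and I differed in 22 features, 7 higher and 15 lower at stage II. Stages III and II differed in 28 features, 10 higher and 18 lower at stage III. Any difference among the 3 stages was found for 209 features by the F test. The numbers at an unadjusted p under 0.05 were 368 for II against I, 778 for III against I, 404 for III against II and 687 for the F test. In simulated data with changes of 0.5 log2 units, 13.4% were recovered for II against I, 8.96% for III against I, 29.9% for III against II and 5.97% by the F test. For changes of 1 log2 unit these were 64.2%, 71.6%, 79.1% and 56.7%. The shares at 0.5 stand for 9, 6, 20 and 4 of 67 changed features, from a single simulated data set per comparison. Differences in recovery between the comparisons are therefore imprecise.

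**Figure D1:**
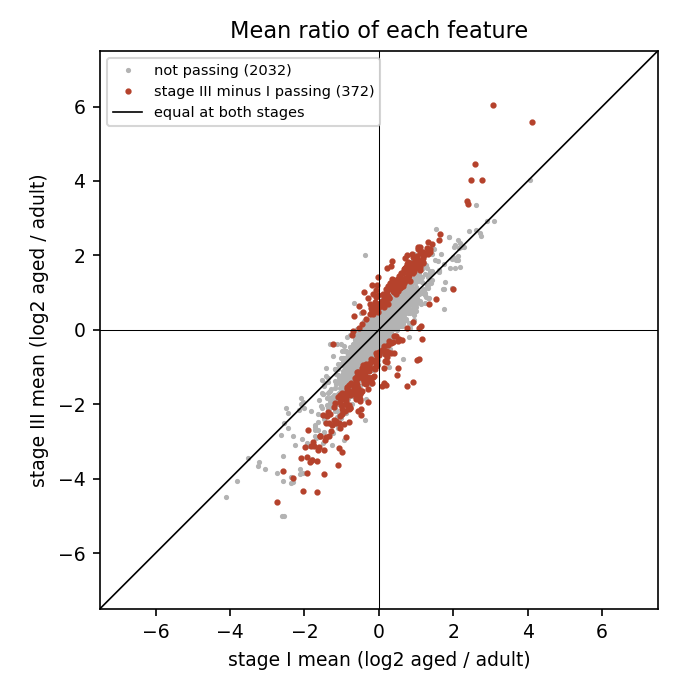
Mean log2 ratio of aged over adult RNA at stage III (vertical axis) against stage I (horizontal axis), 1 point per tested feature, with the 372 features whose stage III minus stage I difference passed in red, the other 2032 in grey and the line of equal ratios in black. Most red points lie farther from 0 on the stage III axis than on the stage I axis.

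The ratios were wider at later stages over the whole array. The width, as the slope of an array on the mean of all 9, was 0.78 ± 0.19 at stage I, 1.02 ± 0.05 at stage II and 1.20 ± 0.07 at stage III (SD, n = 3 each). The share of features more than 1 log2 unit from 0 was 16.3% ± 6.9 at stage I, 26.5% ± 2.3 at stage II and 32.4% ± 1.6 at stage III (SD, n = 3 each, 1621 features measured on every array). A linear trend of width over the stages had an exact permutation p of 0.00238 (two-sided, 1680 assignments of the 9 arrays, 0.0095 after Benjamini-Hochberg adjustment over 4 tests). This test and the pairwise tests below take the arrays as independent. The design text counts 7 aged rats for the 9 arrays, so these p-values do not hold over rats. The pairwise exact tests gave p = 0.20 for II against I, 0.10 for III against I and 0.10 for III against II. After adjustment these were 0.20, 0.13 and 0.13, and 0.10 is the smallest unadjusted p that 3 against 3 arrays allow. The difference of III minus I held in both dye orientations, at 0.36 for the arrays with aged RNA in Cy5 (2 per stage) and 0.55 for the swapped arrays (1 per stage). Stage I replicate 2, at 0.98, was wider than the other stage I arrays, at 0.74 and 0.61.

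**Figure D2:**
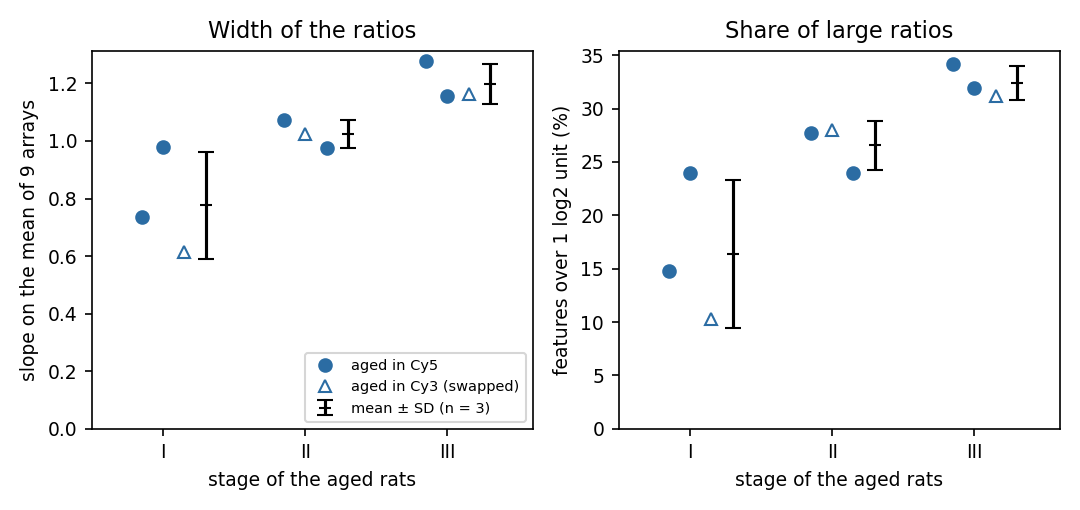
Width of the log2 ratios of each array (left, slope on the mean of 9 arrays, no unit) and percent of the 1621 features measured on every array that lay more than 1 log2 unit from 0 (right), by stage, with circles for arrays with aged RNA in Cy5, triangles for swapped arrays and bars for mean ± SD of 3 arrays. All 3 stage III arrays, at widths of 1.16 to 1.28, lie above every stage I array.

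Fewer features differed between stages III and I once the widths were evened out. After quantile normalization between arrays 29 features passed, 25 of them among the 372. After scaling to one median absolute ratio 48 passed, 29 of them among the 372. In each case the loss of calls came with the removal of width differences, whatever their origin. An even scaling of an array moves its largest ratios most, so by arithmetic it can create, remove or turn a stage difference of a feature far from 0, and the values of single features under it are no evidence about those features. The same arithmetic bears on the values as deposited. Mean widths of 0.78 at stage I and 1.20 at stage III alone give a feature far from 0 a stage difference. The deposited differences below therefore cannot be read as specific to these features either. RNABU29 was 1.48 ± 0.22 higher at stage III than at stage I as deposited (SE, limma adjusted p = 0.0051), but stood at -0.36 ± 0.17 after quantile normalization (adjusted p = 0.26) and at -0.60 ± 0.33 after scaling (adjusted p = 0.35). RNABO13 was 2.96 ± 0.48 higher as deposited (SE, limma adjusted p = 0.0074), with 1.12 ± 0.37 after quantile normalization (adjusted p = 0.13) and 1.08 ± 0.49 after scaling (adjusted p = 0.26). RNABQ01 did not pass as deposited at -0.39 ± 0.21 (SE, limma adjusted p = 0.22), and turned to 1.52 ± 0.30 after scaling, which passed (adjusted p = 0.030), and to 0.94 ± 0.27 after quantile normalization (adjusted p = 0.099). RGIBC39 did not pass in any of these, with -2.42 ± 0.99 as deposited (SE, limma adjusted p = 0.12), -1.03 ± 0.81 after scaling (adjusted p = 0.51) and -0.85 ± 0.68 after quantile normalization (adjusted p = 0.50). It passed with array weights and with the SAM-type test (-2.72, adjusted p = 0.032, and q = 0.046), and without stage I replicate 2 (-3.41, adjusted p = 0.017). Without stage III replicate 1 it shrank to -1.33 and did not pass. Its limma adjusted p reached 0.34 when single arrays were left out. The split of calls between stages also moved with scaling. For III against II it was 2 higher and 17 lower after quantile normalization, and 2 higher and 16 lower after scaling. For II against I it was 5 higher and 21 lower after quantile normalization, and 8 higher and 27 lower after scaling.

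With a common dye term, 333 features differed between stages III and I, 11 between II and I, and 24 between III and II. The 6 arrays with aged RNA in Cy5 gave 6, 4 and 0 features for these comparisons among 1673 tested, and the last had 150 features at an unadjusted p under 0.05 in limma. The swapped arrays, 1 per stage, allow no test on their own. Single arrays weighed on the stage counts. For III against I, 626 features passed without stage I replicate 2, 136 without stage I replicate 1, 108 without stage I replicate 3, and 167, 233 and 155 without stage III replicates 1, 2 and 3. For III against II, 0 passed in limma without stage II replicate 3 or without stage III replicate 3, with 272 and 292 at an unadjusted p under 0.05, and 76 passed without stage I replicate 2. For II against I, 295 passed without stage I replicate 2 and 6 to 13 without any other array. For the F test, 589 passed without stage I replicate 2, 81 and 64 without stage I replicates 1 and 3, 148, 156 and 103 without stage II replicates 1, 2 and 3, and 93, 87 and 45 without stage III replicates 1, 2 and 3.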

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

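The tests of array width by division and of a single linear gain were chosen after the results were seen, while the tests of a curved gain, of the number of measured features and of other splits were set out before. The groups hold 3 arrays each, too few for a test of single arrays that stand apart, so these results were picked out because a test found a difference between stages.

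Stage III differed from stage I in 372 features, stage II from stage I in 22, stage III from stage II in 28, and any stage from another in 209. RNABU29 and RNABO13, which had the largest rises over all stages among features with 1 sign on every measured array, also differed between stages III and I. RNABU29 was 1.48 ± 0.22 log2 units higher at stage III (SE, limma adjusted p = 0.0051), and RNABO13 was 2.96 ± 0.48 higher (SE, limma adjusted p = 0.0074). Neither passed after settings that even out array widths, which by arithmetic move the largest ratios most and so say nothing about single features. For features so far from 0, the deposited differences cannot be told apart from the wider ratios of stage III.

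The pattern weighed is that ratios were wider at stage III than at stage I, and division of each array by its width gave 35 calls, 25 of them among the 372, which restates the pattern, while division by the width of the 1327 features measured on every array and without a call gave 31, 30 of them among the 372, so a width shared with features outside the calls may account for most of them (unadjusted p under 0.05 for 556 features, 778 as deposited). A single linear gain per array, from scanning or hybridisation, is argued against as the whole stage difference. After removal of each array's slope, stage III minus I residuals correlated at 0.62 between the dye orientations across 1621 features (0.61 with ID series medians removed), and a curved gain is argued against as the whole by a correlation of 0.52 among the 531 features with a mean ratio within 0.3 of 0. The number of measured features stays open, because its rank correlation with width over 9 arrays was 0.13 with a 95% interval from -0.58 to 0.73 (permutation p = 0.74, Pearson r 0.18, permutation p = 0.64, and -0.10 without the 2 arrays farthest from the median number). The severity of decline, the individual rats behind each stage and an unrecorded day or batch shared by the arrays of a stage also stay open and were not tested apart. The chip numbers in the sample titles run in stage order, so they cannot separate a batch from stage.

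For any difference among the stages, 1 of 100 splits into 3 groups of 3 arrays, the real one, reached 209 features. The highest other split gave 17. Chance can be excluded only for arrays taken as independent, and not over rats. The design text counts 7 aged rats for 9 arrays, so some arrays must share rats. For the pairs of stages the 10 splits are too few for a share under 0.05. The real split gave 372, 22 and 28 features for III against I, II against I and III against II, and 1 of 10 splits, the real one, reached each of these. The highest other splits gave 3, 0 and 0 in limma, with up to 330, 441 and 124 features at an unadjusted p under 0.05, against 778, 368 and 404 in the real split. For II against I, the split that exchanged stage I replicate 2 with stage II replicate 3 thus exceeded the real one at the unadjusted threshold.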

How the results depend on the processing

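The rise of the counts against adult over stages I, II and III, from 1172 to 1499 and 1659, shrank when widths were evened out. The counts were 1405, 1479 and 1474 after scaling to one median absolute ratio. They were 1406, 1470 and 1486 after quantile normalization, and 1415, 1425 and 1453 after division by width. Over all stages and at each single stage, counts against adult muscle stayed within 1.5 times the main value, except as follows. With the sign of the swapped arrays turned, all 8 counts were 0 in limma (0 to 27 features at an unadjusted p under 0.05). This follows from arrays of 1 stage then opposing one another. Without the swapped arrays the counts were 1229, 735, 918 and 1044 for all stages, I, II and III against adult, and 4, 6, 0 and 5 for II against I, III against I, III against II and the F test, from 1673 testable features. The plain t-test gave 1 (651 unadjusted), 497 and 857 for stages I, II and III. It gave 0 (292 unadjusted), 7 and 3 for II against I, III against I and III against II. At an adjusted p under 0.01 the counts were 775 for stage I and 5, 49, 0 and 22 for the stage differences and the F test, in the order above (404 unadjusted for III against II). At 0.10 those were 51, 589, 70 and 461. Scaling to one median absolute ratio gave 35, 48, 18 and 71 for them. Quantile normalization gave 29 for III against I and 50 for the F test. Array weights raised them to 155, 675, 90 and 597, with stage I replicate 2 weighted lowest at 0.31. A dye term gave 11 for II against I. Fits restricted to the 2 stages gave 7, 188 and 51. The SAM-type test gave 64 for III against II, 412 for III against I and 23 for II against I. A looser filter gave 126 for the F test. Of the alternatives added after seeing the data, removal of ID series medians gave 35 for II against I, and division by width gave 35 (25 among the 372), 12 and 54 for III against I, III against II and the F test. The turned swapped arrays, the settings that even out widths and the other thresholds change calls by construction. For the others the cause was not tested. Fits restricted to single stages gave 806, 1560 and 1651 for stages I, II and III against adult. Restricted fits raised III against II, which leaves out stage I, and lowered the pairs with stage I. Widths varied most at stage I, with an SD of 0.19 against 0.05 at stage II and 0.07 at stage III. Whether the spread of stage I explains these shifts was not tested.

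Leaving out 1 array gave 1459 to 1826 features over all stages, 815 to 1139 at stage I, 1168 to 1465 at stage II and 1317 to 1621 at stage III, from 1814 to 2391 testable features. It gave 6 to 295 for II against I, 108 to 626 for III against I, 0 to 76 for III against II and 45 to 589 for the F test. The highest value of each of these 4 came without stage I replicate 2. The 4 features named by ID kept their direction over all stages in each alternative that could test them, and passed in all of these except with the swapped arrays turned (adjusted p up to 0.86). They were chosen as large passing changes with 1 sign on every measured array, so this outcome was largely set by the choice. The stage III minus stage I difference of RNABU29, 1.48 as deposited, turned to -0.60 after scaling, -0.36 after quantile normalization and -0.74 after division by width, which follows from evening out widths for a feature so far from 0 and is no evidence about the feature. It fell short of the threshold without the swapped arrays (1.19, adjusted p = 0.076), with the plain t-test (adjusted p = 0.10) and with the swapped arrays turned (0.11, adjusted p = 1.00). That of RNABO13, 2.96 as deposited, was 1.08, 1.12 and 1.04 under the 3 settings that remove width and did not pass there, with the plain t-test (adjusted p = 0.18) or with the swapped arrays turned (1.07). RNABQ01, at -0.39 as deposited, turned to 1.52 after scaling, which passed (adjusted p = 0.030), 0.94 after quantile normalization, 1.69 after division by width and 0.015 with the swapped arrays turned, and these last 3 did not pass. For RNABQ01, with stage means of -4.10, -3.89 and -4.49 as deposited, the scalings make the difference by the same arithmetic. Leaving out 1 array kept RNABU29 and RNABO13 past the threshold where they could be tested. No paired analysis was possible because the labels give no replicate numbers shared between stages. Signal over background is not part of the values used, so dim spots cannot be told from bright ones.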

Other observations

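The tests of a dye bias, of a shared adult RNA, of clones grouped by relation and of series split by their number of leading letters were chosen after the results were seen, while those of a bias bound to a dye channel and of single arrays were set out before.

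The features with IDs that start with MKA, a group chosen after the values were seen and not tested as one, had low ratios in the comparison with adult muscle. Of 192 such features 23 were testable, and 22 passed over all stages, 20 lower and 2 higher in aged muscle (limma), where 78.5% of all tested features passed. Their median ratio was -1.81, and single features ranged from -3.09 to 1.33. They form 2 of the 6 series whose IDs have 4 leading letters, with stage III minus II medians of -0.48 and -0.70. What the prefix stands for is not given in the sources used here. At the other end of agreement between stages, 24 features passed against adult in opposite directions at 2 stages, and 21 of them also passed the F test among stages. Their largest difference between stages was 2.33 log2 units.

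The second pattern weighed is that 1886 of 2404 features differed between aged and adult muscle. A dye bias constant over stages, with swapped arrays deposited without inversion, would also make all arrays alike, but stage differences would then run in opposite directions in the 2 dye orientations. After removal of the common pattern they ran together, with a mean correlation of 0.53 over the 3 pairs of stages, where the 5 other ways to assign the swapped arrays to stages gave -0.28 to 0.11. These 6 assignments are too few for a share under 0.05, since the real one alone makes 0.167. Only a dye bias constant over stages is addressed by this. One shared adult RNA that happens to deviate stays open, because the smallest covariance between stages, 0.54 beyond the simulated one, depends on an assumed adult spread that these arrays do not measure. Age and any handling that differed between the aged and adult RNA stay open as well.

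Exchange of aged and adult on single arrays gave as many features in 1 of 100 patterns, the real one (highest other 1393), so over all stages chance can be excluded only for arrays taken as independent, and not for adult or aged RNA that arrays share, while for the single stages the 4 patterns are too few for a share under 0.05 (1 of 4 reached the real 1172, 1499 and 1659, and the highest others gave 14, 0 and 0).

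The third pattern is that IDs which share their leading letters, called a series here, moved together. Series explained 16.7% of the variance of stage III minus II ratios across 2404 features in 65 series, against at most 4.69% in 1000 shuffles of the values (permutation p = 0.001, the smallest these can give, and the same for all 7 contrasts after Benjamini-Hochberg adjustment, with 4.77% to 11.8% for the other 6). A printing or spatial bias bound to a dye channel would change sign on the swapped arrays. As the whole pattern it is argued against by a correlation of series medians of 0.55 between dye orientations over the 63 series of at least 10 tested features (permutation p = 2e-05, Spearman rho 0.32, permutation p = 0.0116). All 6 series of 4 leading letters lay below 0 in both orientations, 1 of them at only -0.03 on the swapped arrays. They were grouped after the values were seen, so their shared sign is no separate evidence. The bias stays open for the 57 series of this size with 5 leading letters. There r was 0.12 (permutation p = 0.364, rho 0.11, permutation p = 0.419), and 30 had the same and 27 opposite signs. A division of these made after the values were seen decides nothing. It gave r -0.31 for the 23 that start with RNAB (permutation p = 0.144, 15 opposite signs) and 0.55 for the other 34 (permutation p = 0.00072, rho 0.46, permutation p = 0.0063, 12 opposite signs). A bias of single arrays is argued against by 13.4% as the lowest share when each of the 6 arrays was left out in turn. Clones of related genes grouped in a series stay open because 0 features could be paired with a gene. A difference between the stages themselves stays open as untested. Array width and a batch shared by the arrays of a stage were not tested for this pattern and stay open too.

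The 6 series with 4 leading letters stood apart in this, a grouping chosen after the values were seen, so no test is given. Their 170 tested features had a median stage III minus II ratio of -0.41 and lay below 0 in 81.2% of cases. The values were 0.04 and 45.8% for the 2234 features of the series with 5 leading letters. Over all stages the median ratio to adult was -0.63, against 0.02 with 5 leading letters. Wider ratios at stage III lower such features by arithmetic, and this share was not separated. The series RNAA, at -0.07 over all stages, still had a stage III minus II median of -0.30. The 6 series held 14 of the 18 features that passed as lower at stage III than at stage II. Among features with 5 leading letters series still explained 7.62% of the variance, against at most 4.32% in shuffles.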
